A study of Rattus norvegicus with 12 samples.

How the data were processed

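RNA sequencing was run on lumbar spinal cord (segments L4 to L6) of 12 rats collected on postoperative day 10. The titles put 4 libraries in each of 3 groups. In Sham the sciatic nerve was exposed and not ligated, in CCI it was ligated, and in CCI+THP it was ligated and the rats also received THP, which from the series title is levo-tetrahydropalmatine, an alkaloid. RNA was extracted with TRIzol, libraries were made with a NEBNext Ultra RNA kit for Illumina, and sequencing was on a HiSeq instrument with a single-read cluster kit, per the labels' protocols and the design text. The design text gives 4 rats per group, so each library was taken as 1 animal.

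The deposited files hold estimated counts, 1 whole number per Ensembl transcript and library, with no scaling for depth or transcript length; they needed no rounding. All 12 files list the same 41078 rows. Their identifiers are rat transcript identifiers with a version, although the file headers call them gene identifiers, so every count here is listed for a transcript. How reads that fit several isoforms were assigned is not given in the sources used here. The submitters' processing notes name the genome build rn4. The aligner, the counting tool and the annotation release are not given in the sources used here. The series' design text speaks of intensities normalized by a robust multi-array average, an array method, and the whole-number deposited counts do not carry that scale. Among deposited counts from 8 to 40, multiples of 4 were on average 1.25 times as frequent as the adjacent values (range over the 12 libraries 1.18 to 1.34), and the other even values 1.07 times. A deposited count is therefore not taken as 1 independent read, no counting interval is given for single libraries, and errors are spreads between animals.

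No table used here pairs these transcript identifiers with gene symbols: 0 of the 41078 matched the symbol table at hand, whose Ensembl column is empty. The 55 gene lists and cell type markers that were fixed before the data were examined, including a list for the genes in the series title (Clec7a, MAPK, NF-κB and NLRP3 inflammasome members), were for this reason not analysed here. Marker checks for other cell types or for tissue from outside the cord were not made either. Transcripts are given by identifier with no gene name, location or strand, and sums over the isoforms of a gene were not possible. A transcript that changes while another isoform of its gene changes the opposite way cannot be told from a gene that changes.

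Library totals ran from 82.9 to 110.8 M (mega) estimated counts. Transcripts were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 24037 and set aside 17041 rows holding 0.0591% of all counts; 8256 rows were at 0 in every library. Counts were scaled with TMM factors (0.975 to 1.02). The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with 1 fit over all 12 libraries, the group as the only factor, and Benjamini-Hochberg adjustment over the 24037 transcripts, two-sided, at 0.05. Standard errors of log2 fold changes were taken as the absolute fold change divided by the square root of F, and 95% intervals from the corresponding t distribution. CPM values (counts relative to the library total) are TMM-scaled, and log2 CPM has a prior count of 2. Where all 4 libraries of a group were at 0, the fold change is a bound, the other group's mean over a floor of 12 counts per library. The floor is 3 fragments if a fragment is worth 4 counts. Single libraries can lie nearer to the floor than the mean. This floor was set after the data were seen, and such bounds cover counting error only.

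The fixed rule for naming took, per comparison and direction, the largest fold changes among transcripts past 0.05 whose 4 values in each group did not overlap. The rule left out features without a gene symbol. None has one here, so that part was set aside after the data were seen, and the first 2 transcripts per direction are given in place of up to 10. On data simulated from the real means, dispersions and library sizes with 200 of 24037 transcripts changed in CCI against Sham, edgeR recovered 28.4% of those changed 1.5-fold, 47.8% of those changed 2-fold and 69.7% of those changed 4-fold, with 5 false calls among 102. In the same simulation of CCI+THP against CCI it recovered 20.9%, 52.2% and 65.2% with 3 false calls among 95, and of CCI+THP against Sham 16.4%, 44.8% and 69.7% with 2 among 89. DESeq2 (1.42.0), which left 124 adjusted p-values as NA in CCI against Sham, made 77 false calls among 195, 49 among 171 and 51 among 162 in these simulations, so its larger counts are given only as an alternative. The simulated counts were drawn with dispersions estimated by edgeR. Unchanged data drawn this way had a mean within-group variance of log2 CPM of 0.565, against 0.667 in the real data. The recovery and false calls of each tool may therefore differ in the real data.

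Alternatives were other size factors, no filter, a filter at a mean CPM of 5, the replicate number as a block, limma voom (3.58.1) with library quality weights, a robust fit, DESeq2, a fit of only the 2 groups compared, other thresholds, and each library left out. Library totals as the only scaling, fold changes fitted by edgeR for the split CCI libraries, counts divided by 4, libraries thinned to the smallest total, and the count of transcripts higher in both ligated groups were added after the data were seen. Within groups, the 18 pairs of libraries differed by 15.4 to 38.8 times the spread expected from sampling (chi-square per degree of freedom, counts divided by 4), so no library was treated as a repeat of another. The files held 0 further columns of per-sample values.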

Results

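Transcript abundance was measured by RNA sequencing in the lumbar spinal cord of 12 rats, 4 with sham surgery (Sham), 4 with sciatic nerve ligation (CCI, a rat model of neuropathic pain) and 4 with ligation and treatment with levo-tetrahydropalmatine (CCI+THP). Estimated counts per library totalled 93.5 ± 4.99 M (mega) in Sham, 87.7 ± 5.67 M in CCI and 96.6 ± 10.8 M in CCI+THP (mean ± SD, n = 4 each). Between 27223 and 28065 transcripts had at least 1 count in a library, and 24037 were tested. The 10 most abundant transcripts held 13.8 ± 0.951% of the counts in Sham, 12.8 ± 1.24% in CCI and 14.1 ± 0.964% in CCI+THP (SD, n = 4). Pearson correlations of log2 CPM between libraries, computed across transcripts, had a median of 0.941 within groups (18 pairs) and 0.939 between groups (48 pairs).

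The 3 groups differed in 179 of 24037 transcripts (edgeR quasi-likelihood F test over all groups, Benjamini-Hochberg adjusted p under 0.05). This count was 98, 81 or 83 without Sham replicate 2, 3 or 4, and 114 without CCI+THP replicate 2. Both ligated groups stood apart from Sham as whole profiles. The mean distance between libraries (root mean square difference of log2 CPM) was 1.18 between CCI and Sham and 1.17 within them, a difference of 0.0136 (exact permutation test, one-sided, p = 0.0286, the smallest that the 70 assignments allow, adjusted over the 3 comparisons 0.0429). For CCI+THP against Sham the difference was 0.0235 (exact permutation p = 0.0286, adjusted 0.0429). For CCI+THP against CCI it was 0.000865 (exact permutation p = 0.429, adjusted 0.429).

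Nerve ligation was followed mainly by higher transcript levels. In CCI against Sham 140 transcripts rose and 4 fell, so 97.2% of the 144 changes were increases. The transcripts that rose did so by a median of 1.75-fold (median log2 fold change 0.81, also with the 2 transcripts at 0 in all Sham libraries set to their bound). Of the 144, 101 changed at least 1.5-fold and 49 at least 2-fold, and in all 144 the 4 CCI values lay entirely above or below the 4 Sham values. Such separation was found for 5.76% of all transcripts tested, against 2.86% given by chance. The changed transcripts had a median abundance of 15.2 CPM (quartiles 6.5 and 34.6), against 7.66 CPM for all transcripts tested. The median log2 fold change of all transcripts was -0.00302 after TMM scaling, which centres it, and 0.02 with library totals as the only scaling. At an unadjusted p under 0.05 there were 2133 transcripts, 1259 higher and 874 lower in CCI, where the other splits of the same 8 libraries gave 694 to 1867.

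ENSRNOT00000001996.4 was the transcript with the smallest p of the comparison. It fell from 47.5 ± 11.9 CPM in Sham to 2.86 ± 0.478 CPM in CCI (SD, n = 4), a log2 fold change of -4.06 ± 0.20 (SE; edgeR adjusted p = 9.76e-06). ENSRNOT00000032780.7 fell from 3.63 ± 0.463 CPM in Sham to between 0 and 2 counts per CCI library (edgeR adjusted p = 0.00964). The increases with the largest fitted fold changes were in scarce transcripts. ENSRNOT00000078017.1 was at 0 in all 4 Sham libraries and at 1.2 ± 0.646 CPM in CCI (edgeR adjusted p = 0.0399). Its CCI mean was 9.24-fold above the Sham floor of 0.13 CPM, and its lowest CCI library was at 0.378 CPM. ENSRNOT00000011073.5 was at 0 in Sham and at 0.423 ± 0.286 CPM in CCI, a group mean 3.26-fold above the floor (edgeR adjusted p = 0.0279). CCI replicates 3 and 4 lay near that floor, both at 0.21 CPM, and replicate 2 was highest at 0.815 CPM. With only the 8 libraries of these groups in the fit, 76 transcripts passed, 71 of them higher, and neither of the last 2 increases did. Leaving out any 1 of the Sham libraries also ended both of these calls, as did CCI replicate 1, 3 or 4 for ENSRNOT00000078017.1 (edgeR adjusted p 0.0684 to 0.143 over these 7 fits) and CCI replicate 1 or 2 or CCI+THP replicate 3 for ENSRNOT00000011073.5 (0.0506 to 0.0827). The call of ENSRNOT00000032780.7 was lost with limma voom (adjusted p = 0.635, lowest over its alternatives 2.86e-10, from DESeq2). The count fell by more than 1.5 times without Sham replicate 3 (82), Sham replicate 4 (72), CCI replicate 1 (76) or CCI replicate 2 (92).

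**Figure D1:**
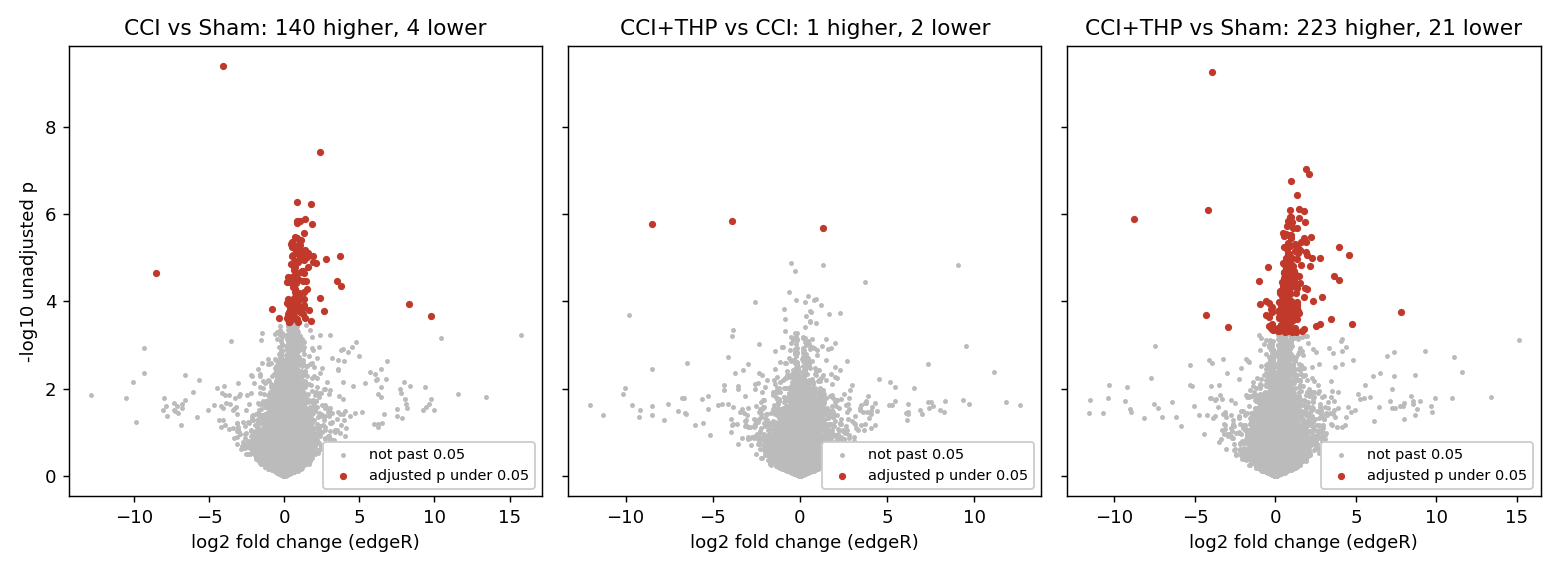
Each point is 1 of the 24037 transcripts tested, with the edgeR log2 fold change on the x axis and -log10 of the unadjusted p on the y axis; red points have an adjusted p under 0.05. Increases dominate among the red points in both comparisons with Sham (140 of 144 and 223 of 244), and 3 transcripts pass between the ligated groups.

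The treatment was tested by comparing CCI+THP with CCI, both ligated. In this comparison 1 transcript rose and 2 fell. ENSRNOT00000025580.7 rose from 2.64 ± 0.442 CPM in CCI to 6.77 ± 0.887 CPM in CCI+THP (SD, n = 4), a log2 fold change of 1.35 ± 0.15 (SE; edgeR adjusted p = 0.0163). Its level in Sham was 1.84 ± 0.17 CPM, so the treated group lay farther from Sham than CCI did. ENSRNOT00000061402.5 fell from 0.579 ± 0.069 CPM to 0.0377 ± 0.0203 CPM (edgeR adjusted p = 0.0163), against 0.703 ± 0.146 CPM in Sham. Its fitted log2 fold change was -3.92 ± 0.42 (SE), and -3.37 with counts divided by 4. The CCI+THP libraries held only 1 to 5 counts each, below the floor, which averaged 0.125 CPM in that group. The size of this fall is therefore less certain than the SE shows. ENSRNOT00000015692.2 fell from 0.485 ± 0.241 CPM in CCI to 0 in all 4 CCI+THP libraries (edgeR adjusted p = 0.0163). Its CCI mean was 3.88-fold above the CCI+THP floor of 0.125 CPM. CCI replicate 4 was at 0.844 CPM and the other CCI libraries between 0.342 and 0.401 CPM. Its level in Sham was 0.599 ± 0.162 CPM. None of these 3 transcripts had passed in CCI against Sham.

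At an unadjusted p under 0.05, 1672 transcripts differed between CCI+THP and CCI, 834 higher and 838 lower. The other splits of the same 8 libraries gave 770 to 1717, so this count was within their range. It lay near the top: 2 of the 35 splits, the real one included, gave at least as many. DESeq2 called 155, 77 higher and 78 lower, and limma voom with quality weights called 1. With only the 8 libraries of the 2 groups in the edgeR fit, 2 transcripts passed, and 0 of these were among the 3. With a filter at a mean CPM of 5 no transcript passed by edgeR; the 3 transcripts lie below that mean and were not tested there. The edgeR count fell to 0 without Sham replicate 1, Sham replicate 3, CCI replicate 1 or CCI+THP replicate 3. It was 1 without CCI replicate 4 or CCI+THP replicate 4, 5 without Sham replicate 2 or CCI replicate 2, and 7 without CCI+THP replicate 1. The call of ENSRNOT00000025580.7 was lost without Sham replicate 1 or 3, CCI replicate 1 or 4, or CCI+THP replicate 2, 3 or 4 (edgeR adjusted p 0.0521 to 0.1). That of ENSRNOT00000061402.5 was lost without these libraries except CCI+THP replicate 2 (0.053 to 0.0885), and that of ENSRNOT00000015692.2 without Sham replicate 1 or 3, CCI replicate 1, or CCI+THP replicate 3 or 4 (0.0506 to 0.062), and also with counts divided by 4 (0.0578).

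**Figure D2:**
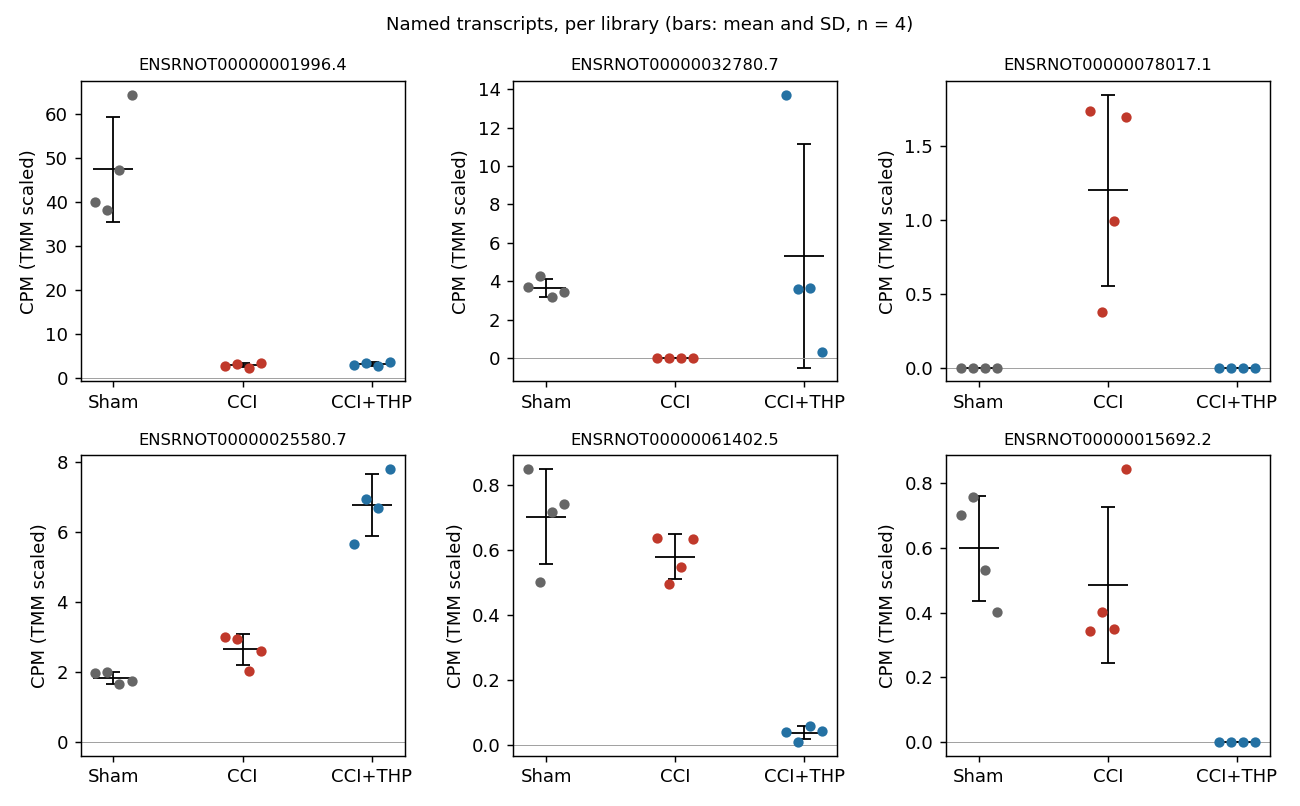
TMM-scaled CPM of 6 named transcripts in each library (points), with the mean and SD of each group (n = 4, y axes on separate scales). The upper row shows transcripts called in CCI against Sham, with ENSRNOT00000001996.4 near 3 CPM in both ligated groups; the lower row shows the 3 called in CCI+THP against CCI.

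The comparison of CCI+THP with Sham asked what separated treated, ligated rats from rats without ligation. Here 223 transcripts rose and 21 fell, and the increases had a median of 1.77-fold, also with the transcript at 0 in Sham set to its bound. Of the 244, 171 changed at least 1.5-fold and 86 at least 2-fold. At an unadjusted p under 0.05 there were 2431, 1398 higher and 1033 lower. ENSRNOT00000011073.5, at 0 in Sham, was at 0.303 ± 0.258 CPM in CCI+THP, a group mean 2.33-fold above the floor (edgeR adjusted p = 0.026). That mean rested largely on CCI+THP replicate 4, at 0.685 CPM. The other CCI+THP libraries lay between 0.118 and 0.205 CPM, near the Sham floor of 0.13 CPM. ENSRNOT00000005988.4 rose from 0.0244 ± 0.0289 to 0.684 ± 0.398 CPM (SD, n = 4; edgeR adjusted p = 0.0404), a call that was lost whichever of the 12 libraries was left out (edgeR adjusted p 0.0517 to 0.104). ENSRNOT00000015692.2 was at 0 in all CCI+THP libraries and between 0.403 and 0.758 CPM in Sham (edgeR adjusted p = 0.00227). Its Sham mean was 4.8-fold above the CCI+THP floor. ENSRNOT00000043602.5 fell from 1.67 ± 0.338 to 0.0836 ± 0.0733 CPM (SD, n = 4; edgeR adjusted p = 0.0279). Leaving out any 1 of the Sham libraries ended the calls of ENSRNOT00000011073.5 and ENSRNOT00000043602.5, as did CCI replicate 1 or CCI+THP replicate 1 for the first (0.0506 to 0.0638) and CCI+THP replicate 2 or 4 for the other (0.0539 to 0.109). The count fell by more than 1.5 times without Sham replicate 2 (157), 3 (140) or 4 (115), and without CCI+THP replicate 1 (153), 2 (138) or 4 (144).

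Most transcripts that rose after ligation were also higher than Sham in treated rats. Of the 140, 122 passed in the same direction in CCI+THP against Sham, and 138 had the same sign. The 122 fell to 81, 67 or 62 without Sham replicate 2, 3 or 4, to 69 or 74 without CCI replicate 1 or 2, and to 77 without CCI+THP replicate 2. Independent lists of 140 and 223 transcripts would share 1.3. The median log2 fold change of the 140 against Sham was 0.81 in CCI and 0.82 in CCI+THP. Between CCI+THP and CCI their median was 0.01 (quartiles -0.07 and 0.08), with 61 lower and 79 higher in treated rats. None of the 140 passed as lower in CCI+THP than in CCI over all transcripts tested (edgeR). Adjusted over the list alone, 2 were lower and 0 higher, and at an unadjusted p under 0.05, 6 were lower and 3 higher. DESeq2 called 2 of them lower and 0 higher, and limma voom 0. The list was chosen on the same CCI libraries, so this is not independent evidence. For 115 of the 140 the 95% interval of the log2 difference excluded a return by 0.5 or more of the measured ligation effect. All 4 transcripts that fell in CCI had a higher level in CCI+THP than in CCI, 3 of them at an unadjusted p under 0.05, 1 when adjusted over the list alone and 0 over all transcripts tested (edgeR). Their median log2 fold change against Sham was -2.45 in CCI and -0.35 in CCI+THP. These 4 were also chosen on the same CCI libraries, which favours a higher level in CCI+THP. The rise and the medians are therefore not independent evidence of a return. Of these 4, ENSRNOT00000001996.4 also passed in CCI+THP, where it was at 3.14 ± 0.402 CPM (SD, n = 4; log2 fold change against Sham -3.92 ± 0.20, SE, edgeR adjusted p = 1.31e-05). ENSRNOT00000032780.7 lay at 5.32 ± 5.81 CPM in CCI+THP, with libraries between 0.326 and 13.7 CPM, and did not pass against CCI (edgeR adjusted p = 0.0587). ENSRNOT00000078017.1 was at 0 in all 4 CCI+THP libraries and did not pass against CCI either (edgeR adjusted p = 0.224).

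**Figure D3:**
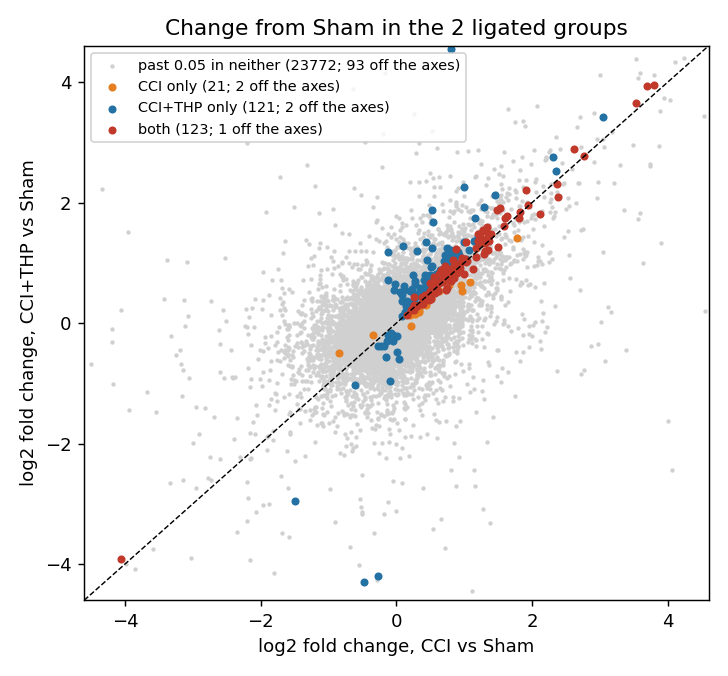
Log2 fold change against Sham in CCI (x axis) and in CCI+THP (y axis) for each transcript tested whose values lie within the axes. The legend counts the transcripts off the axes. Colours mark the comparisons in which a transcript passed 0.05, and the dashed line marks equal change. Of the 123 transcripts that passed in both (122 higher, 1 lower), those within the axes lie along the line.

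The comparisons of both ligated groups with Sham share the Sham libraries. With no effect, simulated data gave a correlation of 0.499 ± 0.015 (SD over 100 data sets) across transcripts, against 0.55 observed, and a covariance of 0.14 ± 0.00622, against 0.205. Transcripts are not independent replicates, and the simulated within-group variance (0.565) was below the real one (0.667). The real variance, pooled over the 3 groups, would give a covariance of 0.167 from shared libraries alone. The variance of the Sham libraries, the ones shared here, was not used on its own. When the Sham libraries were split 2 and 2 so that no library was shared, the correlation was 0.0777 on average (0.0591 to 0.109 over 6 splits) and the covariance 0.0416 for differences of mean log2 CPM. For fold changes fitted by edgeR over the same splits the correlation was 0.122 on average (0.107 to 0.141) and the covariance 0.106 (0.0957 to 0.119). With such splits 9 to 72 transcripts were higher in CCI, 48 to 107 in CCI+THP, and 4 to 26 in both, where independent lists would share 0.0236 to 0.161.

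Whether treatment moved transcripts against the direction of the ligation effect was asked across all transcripts. The log2 fold changes of CCI against Sham and of CCI+THP against CCI had a Pearson correlation of -0.472. Both use the CCI libraries with opposite signs, and simulated data with no effect gave -0.502 ± 0.0139 (SD over 100 data sets). The covariance was -0.1672. The simulation gave -0.142 ± 0.00595. The real within-group variance, pooled over the 3 groups, gave -0.1667 for unchanged groups, a difference of -0.000539. That calculation was added after the data were seen. Only the CCI libraries are shared here, and their own variance was not used. The mean distance within groups was 1.167 for CCI with Sham, 1.159 for CCI+THP with CCI and 1.136 for CCI+THP with Sham. The CCI libraries were thus the most spread, so the pooled variance may understate the size of the chance covariance. The sign of the difference is not settled by it. With the CCI libraries split so that none was shared, the correlation was 0.0178 on average (-0.00924 to 0.051 over 6 splits) for differences of mean log2 CPM, and -0.0288 (-0.0579 to -0.0116) for fold changes fitted by edgeR over the same splits, so its sign depended on the measure of change. By edgeR, 0 transcripts passed in both comparisons. At an unadjusted p under 0.05 there were 414 with opposite signs and 31 with the same sign, DESeq2 called 28 and 2, and limma voom 0 and 0. The shared CCI libraries favour opposite signs in these counts.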

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

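The tests of explanations in this part, the thinning of libraries included, were chosen after the data were seen. Of 31 groups of 4 values examined for a single library far from the others, 2 stood out by Dixon's ratio, where chance flags about 1 in 20. ENSRNOT00000015692.2 was at 0.844 CPM in CCI replicate 4 and between 0.342 and 0.401 CPM in the other CCI libraries. ENSRNOT00000011073.5 was at 0.685 CPM in CCI+THP replicate 4 and between 0.118 and 0.205 CPM in the other CCI+THP libraries.

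The first pattern is that 140 of the 144 changes in CCI against Sham were increases. Chance is argued against as the source of the count. Of the 35 splits of the 8 libraries, 1, the real one, gave as many, and the highest other gave 5. That is the smallest share that 35 splits allow. The other splits mix CCI with Sham, so they are not free of a real difference. The TMM factors as the source are argued against by the 176 calls (173 higher) made with library totals as the only scaling, and a depth difference by the 146 calls (140 higher) made after all libraries were thinned to the smallest total. A shift common to all transcripts cannot be measured from these counts. A biological effect of the ligation is the difference the design names and stays open as a hypothesis; a change in the makeup of the tissue was not tested, because the transcripts have no gene names here.

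The second pattern is that transcripts higher in CCI stayed higher in CCI+THP. A return by 0.5 or more of the rise could be hidden if the same CCI libraries both chose the transcripts and set their level. When 2 of the CCI libraries made the calls (13 to 136 higher transcripts) and CCI+THP was read against the other pair, the median log2 difference lay between -0.112 and 0.18 over 6 runs, against median rises of 0.65 to 1.17 in the unused pair, which argues against that explanation for the list as a whole. Returns of single transcripts stay open. Chance is argued against for CCI+THP against Sham, where 1 of 35 splits gave 244 calls, again the smallest share possible, and the highest other gave 3. Chance cannot be excluded for CCI+THP against CCI. There 4 of 35 splits gave at least the 3 calls of the real one, and the highest other gave 4.

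For the test over all groups, 1 of 100 drawn splits, the real one, gave 179 calls. This is the smallest share that 100 splits allow, so chance is argued against as the source of this adjusted count. The highest other, 124, was the single drawn split that kept the 4 Sham libraries together while mixing CCI with CCI+THP; the 98 that broke up Sham gave at most 7. It shared 117 transcripts with the 179, and 177 of the 179 also passed in CCI or CCI+THP against Sham. At an unadjusted p under 0.05 the margin was small, with 2314 transcripts for the real groups and 689 to 2235 for the other drawn splits. The split with 2235 mixed the groups and gave 2 calls after adjustment. What set its libraries apart was not tested.

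The third pattern is transcripts at no more than 3 counts in all 4 libraries of a group and at 0.3 CPM or more in all 4 of the other. There were 7 between CCI and Sham, where 1 of 35 splits gave as many and the highest other gave 6. This is the smallest share that 35 splits allow, in 1 of 3 comparisons and without adjustment. Whether chance accounts for these 7 is therefore not settled. There were 4 between CCI+THP and CCI and 3 between CCI+THP and Sham, where 5 and 14 of 35 splits gave as many (highest others 7 and 8), so which libraries happened to fall together may account for these. Reads moved between isoforms of a gene could also give such values; this was not tested, because the isoforms of a gene cannot be grouped here.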

How the results depend on the processing

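Library totals as the only scaling, edgeR fold changes for the split CCI libraries, counts divided by 4, thinned libraries and the count of transcripts higher in both ligated groups were chosen after the data were seen; the other settings were fixed before the data were examined. The cause of the differences below was not tested. The count of 144 in CCI against Sham became 651 with DESeq2 (517 higher, 134 lower), 755 at an unadjusted p under 0.05 with a fold of at least 1.5 (568 higher, 187 lower), 76 with only the 2 groups fitted, and 72 to 149 over the 12 libraries left out in turn. The 3 of CCI+THP against CCI became 0 with a mean CPM of at least 5, a filter that removes these 3, 1 with limma voom, 155 with DESeq2, 454 at an unadjusted p with a fold of at least 1.5, and 0 to 7 with a library left out. The 244 of CCI+THP against Sham became 850 with DESeq2 (612 higher, 238 lower), 861 at an unadjusted p with a fold of at least 1.5 (688 higher, 173 lower), and 115 to 241 with a library left out. The 122 higher in both became 366 with DESeq2 and 62 (without Sham replicate 4) to 123 with a library left out; Sham replicates 2 and 3, CCI replicates 1 and 2 and CCI+THP replicate 2 also moved it, to 81, 67, 69, 74 and 77. The 179 of the overall test ranged from 81 to 177, with Sham replicates 2, 3 and 4 and CCI+THP replicate 2 moving it most, to 98, 81, 83 and 114. The covariance of opposite changes less its chance value was -0.000539, with the chance value taken from the variance pooled over the 3 groups. With a library left out it ranged from -0.0176 (without CCI replicate 1) to 0.00414, and it was -0.0159 without CCI replicate 4. With the CCI libraries split, which shares no library, it was 0.00962. When the split used fold changes fitted by edgeR it was -0.0228 (-0.0444 to -0.00951 over 6 splits), so its sign is not settled. With the replicate number as a block, the counts were 109, 0 and 181 for the 3 comparisons, 117 overall and 97 in both; same-numbered libraries did not deviate together (correlations -0.0351 to 0.0311 over 12 pairs, and 2 of 12 libraries correlated best with their own number), so the numbers were not taken to pair the animals. Size factors, library totals, no filter, the robust fit, counts divided by 4 and thinning kept each count within 1.5 times, and no named transcript changed direction in any setting. ENSRNOT00000001996.4 and, against Sham in CCI+THP, ENSRNOT00000015692.2 passed in every setting that tested them; the other named transcripts lost the call in 1 to 16 settings. Alternatives fixed for gene lists, for the genes of the series title and for transcripts of the same symbol were not run, for want of gene names, nor were a pseudocount, quantile normalization and limma without a trend, which apply to normalized units.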

Other observations

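The test in this part was chosen after the pattern was seen. Multiples of 4 were in excess among low deposited counts in all 12 libraries, 1.25 times the frequency of adjacent values on average (1.18 to 1.34), and the other even values were 1.03 to 1.15 times as frequent as theirs. This is consistent with counts computed from coverage in which a sequenced fragment is worth about 4, a hypothesis that the deposited values alone cannot settle. If so, the totals of 82.9 to 110.8 M may overstate the number of sequenced fragments. Dividing the counts by 4 gave 164, 2 and 274 calls for CCI against Sham, CCI+THP against CCI and CCI+THP against Sham, of which 142, 2 and 242 were among those of the undivided counts.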
